A study of Homo sapiens with 6 samples.

How the data were processed

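The series measured RNA from U2OS, an established human osteosarcoma cell line, after transfection with a small interfering RNA against KPNA2 (siKPNA2, 3 samples) or a control siRNA (siNC, 3 samples). Per the labels' protocols, RNA was isolated with TRIzol, poly(A) RNA was selected and fragmented, second strands were marked with dUTP, and paired 150-base reads were sequenced on a NovaSeq instrument. The siRNA sequences, the dose and the time after transfection are not given in the sources used here. The labels number the samples 1 to 3 within each group and do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

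The submitters' processing notes name fastp, HISAT2 and StringTie and the build GRCh38, without versions or roles. The annotation release, the filters and the strand setting of the counting are not given in the sources used here. The deposited table holds 60612 genes with 6 columns of estimated counts, which the deposited values show to be whole numbers, and 6 columns of FPKM. The authors list FPKM as 1e-04 where a gene has 0 counts. No row lacked a gene, and no column of values was left unused.

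The deposited counts are not single fragments. Low values pile up at multiples of 4: in siKPNA2 replicate 1, 1702 genes had 4 counts, against 739 with 3 and 407 with 5. This is the pattern that paired 150-base reads give when coverage is converted to counts with an assumed read length of 75, so that 1 fragment is worth about 4 counts. That conversion was inferred from the values and is not stated in a source. Library totals were 61729140 to 66285112 counts. The floor for a gene at 0 was set at 3 fragments, or 12 counts over a group, and 95% intervals of count ratios are exact binomial (Clopper-Pearson) on counts divided by 4 and summed over the group. They cover counting error only, since the reads carry no molecular identifiers.

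Estimated counts, already whole, were used as deposited, after rounding that changed nothing. Genes were kept by edgeR's filterByExpr and scaled with TMM factors, and edgeR's quasi-likelihood test with robust dispersion compared siKPNA2 with siNC, two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene is said to have risen or fallen where its adjusted p was under 0.05. Adjusted p-values of single genes come from this test unless another is named. Levels are TMM-normalized CPM (each count divided by the scaled library total and multiplied by 1e6), given as mean ± SD over 3 libraries, and the standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

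Before the data were examined, 21 gene lists were fixed. They covered nuclear transport factors, interferon-stimulated genes, DNA replication and G1/S genes, mitosis and G2/M genes, p53 target genes, MYC target genes, NF-kB and inflammatory genes, extracellular matrix and mesenchymal genes, osteoblast lineage genes, ATF4 and unfolded protein response genes, cholesterol synthesis genes, hypoxia and glycolysis genes, ribosomal protein genes, DNA repair genes, apoptosis regulators, lysosome and autophagy genes, mitochondrially encoded transcripts, immediate-early genes, and markers of blood, epithelial and endothelial cells. KPNA2 was left out of every list. Members were matched by the table's gene names or by an older symbol. Lists were tested with limma's camera on voom values with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 21 lists, with camera's estimated correlation and fry beside it. The GO and KEGG terms that the table itself attaches to genes were tested one-sided with Fisher's exact test, for higher and lower genes apart. The background was the tested genes with a term of that kind, terms held 10 to 500 such genes, and adjustment ran over both directions.

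The genes named were chosen by a rule fixed before the data were examined. The rule took KPNA2 and the 10 largest fitted rises and 10 largest fitted falls among genes with an HGNC symbol in the table, an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups. It also took up to 3 members of each list, and of each enriched term named, with the smallest p. Having a symbol was read as a table description that cites HGNC. Where 5 or fewer members of a list changed in a direction, the remaining ones are named too, chosen after their values were seen. The terms named were chosen after the enrichment was seen. The results of some genes that these rules take are not reported here. Also named after their values were seen are matrix genes that fell, the 3 with the smallest p and the collagens. Of the 134 genes taken in these ways, 32 overlap another gene of the table on the same strand and 60 overlap 1 on the other strand, so their reads can be split or shared in ways the table does not show. HBA1 and HBA2, and HBG1 and HBG2, are near-identical copies whose split of reads is uncertain.

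The test was tried on simulated data for the siKPNA2 comparison, with 200 genes changed. With the spread following its trend over level, over 21954 genes, 86% of 2-fold changes and 35% of 1.5-fold changes were recovered and 3 calls (2.4%) were false. With each gene's own spread, over 21948 genes, the shares were 82% and 31%, and 18 calls (13.7%) were false. The simulated spread was re-estimated on counts divided by 4 after a first run had used the deposited scale. The only gene list shifted in a simulation was the only 1 called. Simulated genes were drawn independently, so this could not show false list calls that come from correlation between genes. No pair of libraries of a group agreed within sampling noise, as repeat deposits of 1 library would (chi-square per degree of freedom of 10.1 to 12.8), which does not show whether they came from separate cultures.

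Alternatives fixed before the data were examined were DESeq2's size factors and upper-quartile factors in the same fit, DESeq2's own test, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), no low-count filter beyond 1 count, a mean of at least 5 CPM, dispersion that was not robust, the replicate number as a block, and leaving out each library. Terms of 5 to 200 genes were also tried. Dividing the counts by 4 was added after seeing the data. Coordinates are those of the deposited table on GRCh38. Transcript lengths, GC content, 3′ UTRs and the position of a heptamer in KPNA2 come from GENCODE v29, also GRCh38, whose release may not be the authors'.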

Results

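RNA from U2OS osteosarcoma cells was sequenced after transfection with siKPNA2 or with siNC, 3 libraries each, to find the genes whose transcripts depend on KPNA2. KPNA2 encodes an importin alpha, the adaptor that carries proteins with a nuclear localisation signal to importin beta. The libraries held 61729140 to 66285112 estimated counts, at about 4 counts per fragment, and 28669 to 29309 genes with a count. Correlations of log CPM were 0.968 to 0.971 within groups and 0.949 to 0.955 between groups, across genes, which are not independent replicates.

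KPNA2 itself fell to 2.85% of its siNC level (2.56% to 3.17% at 1 SE). The gene (ENSG00000182481) lies on the plus strand of chromosome 17, 68035708 to 68046842. Its level was 24.5 ± 4.67 CPM (SD, n = 3) in siKPNA2 and 859 ± 22.3 CPM (SD, n = 3) in siNC. The log2 fold change was -5.13 (SE 0.15, edgeR adjusted p = 2.12e-05). The siKPNA2 libraries held 29.4, 20.2 and 23.9 CPM, and the siNC libraries 860, 881 and 837 CPM, in the order of their numbers. The deposited FPKM were 6.91 ± 1.27 in siKPNA2 and 245 ± 5.32 in siNC (SD, n = 3).

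**Figure D1:**
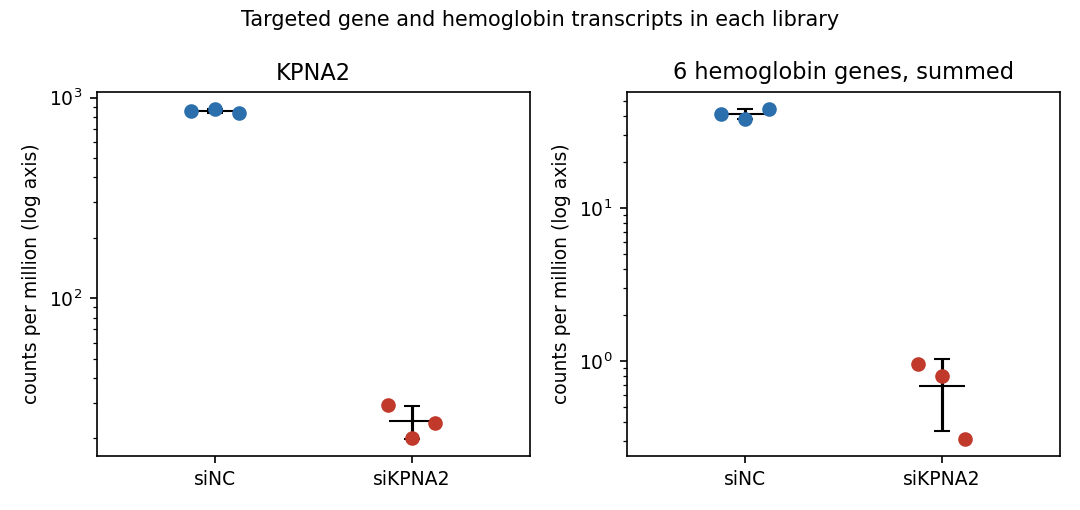
KPNA2 (left) and the sum of 6 hemoglobin genes (right) in each library, in CPM on log axes, with KPNA2 TMM-normalized and the hemoglobin sum not. Points are libraries, horizontal bars are means and whiskers SD (n = 3); KPNA2 was 24.5 against 859 CPM and hemoglobin 0.692 against 41.5 CPM in siKPNA2 and siNC.

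After knockdown GCNA, a germ cell nuclear protein (ENSG00000147174, chromosome X, 71578411 to 71613583), rose from 4.13 ± 1.32 to 43.4 ± 2.74 CPM (SD, n = 3; log2 fold change 3.39, SE 0.25, edgeR adjusted p = 0.000202). COL6A3, a collagen VI chain (ENSG00000163359, chromosome 2, 237324003 to 237414207), rose from 52.8 ± 7.73 to 344 ± 27.4 CPM (log2 fold change 2.70, SE 0.12). The other large rises were in BCL2A1, an anti-apoptotic BCL2 relative (2.59, SE 0.19), the desmosome protein DSP (2.54, SE 0.09), the hair keratin KRT34 (2.49, SE 0.14), KRTAP2-3 (2.46, SE 0.09), ANKRD30B (2.37, SE 0.22), OGFR (2.27, SE 0.08), ADTRP (2.18, SE 0.19) and RNF185 (2.12, SE 0.49), all as log2 fold changes with edgeR adjusted p of 0.0323 or less.

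Among the falls, CAVIN2, a coat protein of caveolae (ENSG00000168497, chromosome 2, 191834310 to 191847088), went from 19.4 ± 1.02 to 1.94 ± 0.469 CPM (SD, n = 3; log2 fold change -3.33, SE 0.19, edgeR adjusted p = 3.68e-05). DDIT4, a stress-induced inhibitor of mTORC1 (ENSG00000168209, chromosome 10, 72273924 to 72276036), went from 82.3 ± 4.14 to 18.5 ± 0.783 CPM (log2 fold change -2.16, SE 0.07). The pro-apoptotic BMF (-2.51, SE 0.25), the potassium channel KCNA2 (-2.41, SE 0.16), the dopamine receptor DRD1 (-2.40, SE 0.28), TMEM158 (-2.26, SE 0.17), the 5-methylcytosine dioxygenase TET1 (-2.23, SE 0.25) and the stress cytokine GDF15 (-2.11, SE 0.15) also fell. HBB and CA1, both abundant in red cells, had the lowest fitted ratios after knockdown among genes with a mean of at least 5 CPM other than KPNA2, and are described with the blood markers. On log2(FPKM + 1), which understates the change of low genes, the log2 fold changes were smaller for GCNA (2.50), DSP (1.43), ANKRD30B (1.56), ADTRP (1.29), CAVIN2 (-2.06), BMF (-1.04), KCNA2 (-0.63), DRD1 (-1.72) and TET1 (-0.82).

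In all, 6099 of 22670 tested genes passed the threshold (26.9%; edgeR's quasi-likelihood test), of which 3201 rose and 2898 fell. A change of at least 2-fold was seen for 1431 genes, 710 higher and 721 lower. The groups did not overlap for 44.9% of tested genes, against 10% by chance. The count of 2-fold changes was 548 among genes with a mean of at least 5 CPM and 306 on log2(FPKM + 1), and the RNF185 call was lost in 7 of 17 alternatives, among them leaving out siKPNA2 replicate 1 or 3 or any siNC library (siKPNA2 60.2 ± 31.0 CPM, SD, n = 3). The longest annotated 3′ UTR of TMEM158 holds TCCGAAA, the 7 bases most associated with a lower level in siKPNA2. Those of COL6A3, RNF185 and CAVIN2 hold TGTCACG, the 7 bases most associated with a higher level. Named genes are marked only for these exact 7 bases, and unmarked ones can still hold related bases.

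**Figure D2:**
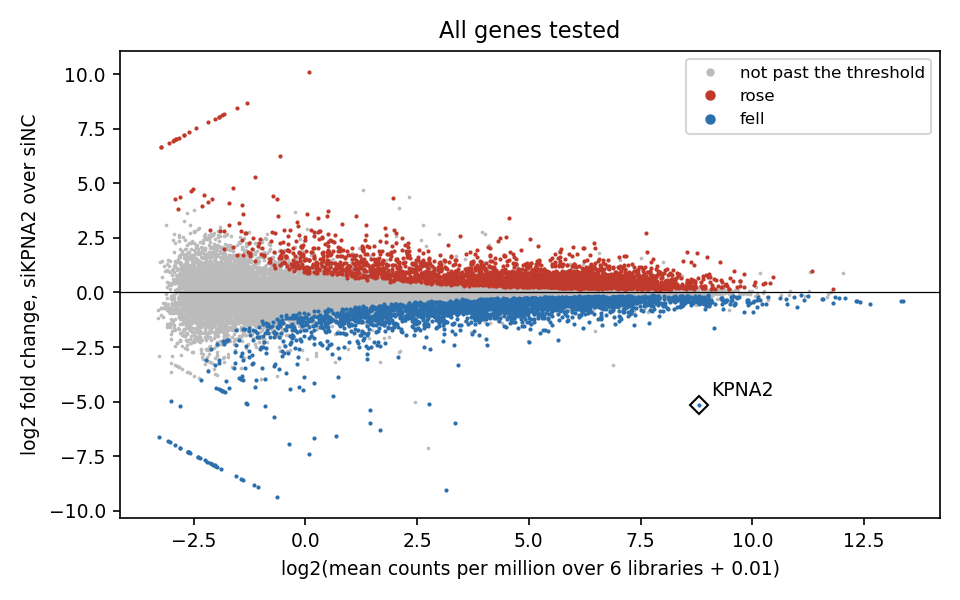
Log2 fold change of siKPNA2 over siNC (vertical) against log2 of the mean CPM over 6 libraries plus 0.01 (horizontal) for the 22670 genes tested. Red points rose (3201), blue points fell (2898), grey points did not pass the threshold, and the diamond is KPNA2 at -5.13; slanted lines of points at the left edge are genes with no counts in 1 group, whose fitted values are no bounds.

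**Figure D3:**
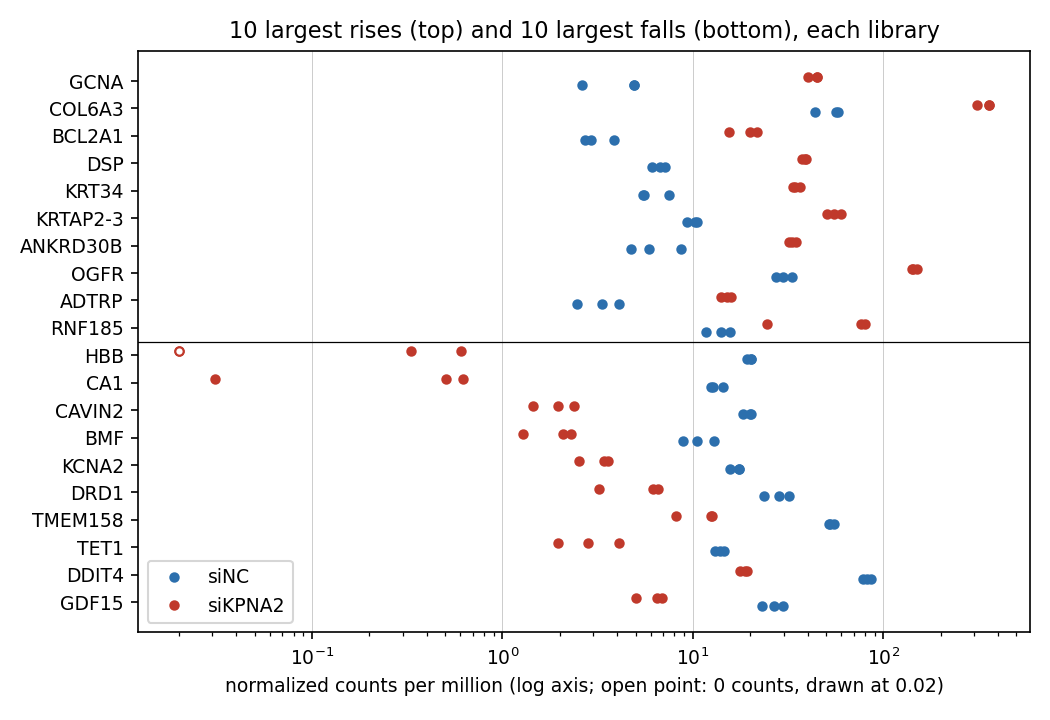
TMM-normalized CPM (log axis) in each of the 6 libraries for the 10 largest rises and the 10 largest falls. Each point is a library, red for siKPNA2 and blue for siNC, and an open point is a library with 0 counts drawn at 0.02; the siKPNA2 points lie on 1 side of the siNC points for every gene, and RNF185 is the most spread of the rises.

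Interferon-stimulated genes and p53 target genes were the lists with the lowest medians among those past the threshold with camera's preset correlation, and neither passed with an estimated one. The camera adjusted p was 1.08e-08 for the interferon list (adjusted p = 0.192 with an estimated correlation) and 2.7e-06 for the p53 list (adjusted p = 0.102 with an estimated correlation). The estimated correlation was 0.084 for the interferon list but 0.001 for the p53 list, under the preset 0.01. The lost p53 call therefore does not come from a higher correlation between its members. Of 42 interferon-stimulated genes tested, 23 fell and 1 rose (26 and 2 adjusted over the list alone), with a median log2 fold change of -0.75. TRIM22, an antiviral ubiquitin ligase, fell (log2 fold change -1.20, SE 0.08), PARP9 went from 54.0 ± 1.99 to 25.9 ± 0.772 CPM (SD, n = 3), and LGALS3BP from 150 ± 3.01 to 82.5 ± 6.39 CPM. The member that rose was IFI44 (log2 fold change 0.30, SE 0.08). Of 29 p53 targets, 19 fell and 5 rose (21 and 5 adjusted over the list alone), with a median of -0.47. MDM2, the ubiquitin ligase of p53, went from 348 ± 14.9 to 207 ± 2.27 CPM, TIGAR from 150 ± 1.90 to 96.8 ± 1.88 CPM, and GDF15 fell as above, while AEN, XPC, SESN2, TNFRSF10B and GADD45A rose. The calls of IFI44, TNFRSF10B and GADD45A were lost in 9, 9 and 10 of 17 alternatives. The siNC libraries, in which both groups were higher, also held hemoglobin transcripts at 41.5 CPM against 0.692 CPM. The longest annotated 3′ UTR of TNFRSF10B holds TCCGAAA.

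Ribosomal protein and mitochondrially encoded transcripts were lower as groups with camera's preset correlation, but not with an estimated one. The camera adjusted p was 1.79e-13 for ribosomal proteins (adjusted p = 0.192 with an estimated correlation) and 1.85e-08 for mitochondrial transcripts (adjusted p = 0.294 with an estimated correlation). Of 49 ribosomal protein genes, 34 fell and RPL11 alone rose (41 and 1 adjusted over the list alone), with a median log2 fold change of -0.35. RPL4 went from 1481 ± 47.7 to 1037 ± 8.80 CPM (SD, n = 3), RPL5 from 635 ± 11.3 to 411 ± 31.9 CPM and RPS23 from 475 ± 16.1 to 343 ± 7.91 CPM. Of 13 mitochondrial transcripts, 12 fell, also adjusted over the list alone, and MT-ND2 did not pass, with a median of -0.37. MT-ND5 (-0.49, SE 0.03), MT-ND6 (-0.52, SE 0.05) and MT-ND4L (-0.52, SE 0.05), subunits of respiratory complex I, had the smallest p.

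The shares of counts moved in the same libraries. Mitochondrial transcripts took 5.15% ± 0.172 of counts in siKPNA2 and 6.62% ± 0.201 in siNC (SD, n = 3), and ribosomal protein genes 2.15% ± 0.095 and 2.76% ± 0.006. Each difference had an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 can give. Noncoding genes of the ribosomal DNA repeat took 1.08% ± 0.144 in siKPNA2 and 0.586% ± 0.304 in siNC (SD, n = 3; exact permutation p = 0.2).

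With camera's preset correlation, but not with an estimated one, hypoxia and glycolysis genes were lower, and MYC targets and lysosome and autophagy genes higher, with members going both ways. The camera adjusted p was 0.0254 for hypoxia and glycolysis (adjusted p = 0.349 with an estimated correlation), 0.015 for MYC targets and 0.0254 for lysosome and autophagy (adjusted p = 0.294 for both with an estimated correlation). The siNC libraries also held more hemoglobin transcripts (41.5 against 0.692 CPM) and a higher mitochondrial share (6.62% against 5.15%). Set against 20 genes matched on length, GC content and level, all 3 lists had differences whose 95% bootstrap intervals included 0. Of 31 hypoxia and glycolysis genes, 14 fell and 4 rose (14 and 5 adjusted over the list alone), with a median of -0.19. BNIP3L, a mitophagy receptor, fell (-0.64, SE 0.05), and PFKL (1.04, SE 0.06), the glucose transporter SLC2A3 (0.67, SE 0.06), ANKRD37, whose 3′ UTR holds TGTCACG, and PFKFB3 rose, the last 2 with calls lost in 6 and 8 of 17 alternatives. Of 30 MYC targets, 11 rose and 3 fell (12 and 5 adjusted over the list alone), with a median of 0.17. TCOF1, a ribosome biogenesis factor, rose (0.94, SE 0.05), as did ODC1 (0.61, SE 0.05), while lactate dehydrogenase LDHA (-0.90, SE 0.07), NPM1 and HSPE1 fell, the last 2 with calls lost in 1 and 6 alternatives. Of 33 lysosome and autophagy genes, 13 rose and 4 fell (13 and 5 adjusted over the list alone), with a median of 0.13. The protease CTSB (1.04, SE 0.09), the transcription factor TFE3 (0.68, SE 0.05) and ATP6V0D1 (0.62, SE 0.06) rose, and LAMP2, ATG5, NPC2 and ATG9A fell, the last 3 with calls lost in 2, 2 and 6 alternatives. None of these 3 calls held among genes with a mean of at least 5 CPM (adjusted p 0.0689, 0.087 and 0.093), and those of hypoxia without siKPNA2 replicate 3 (0.0801) and on log2(FPKM + 0.1) (0.0616) and of lysosome with upper-quartile factors (0.0573) and counts divided by 4 (0.0559) were also lost; over all camera alternatives the adjusted p ran from 0.00339 to 0.349, 0.00121 to 0.294 and 0.00364 to 0.294.

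**Figure D4:**
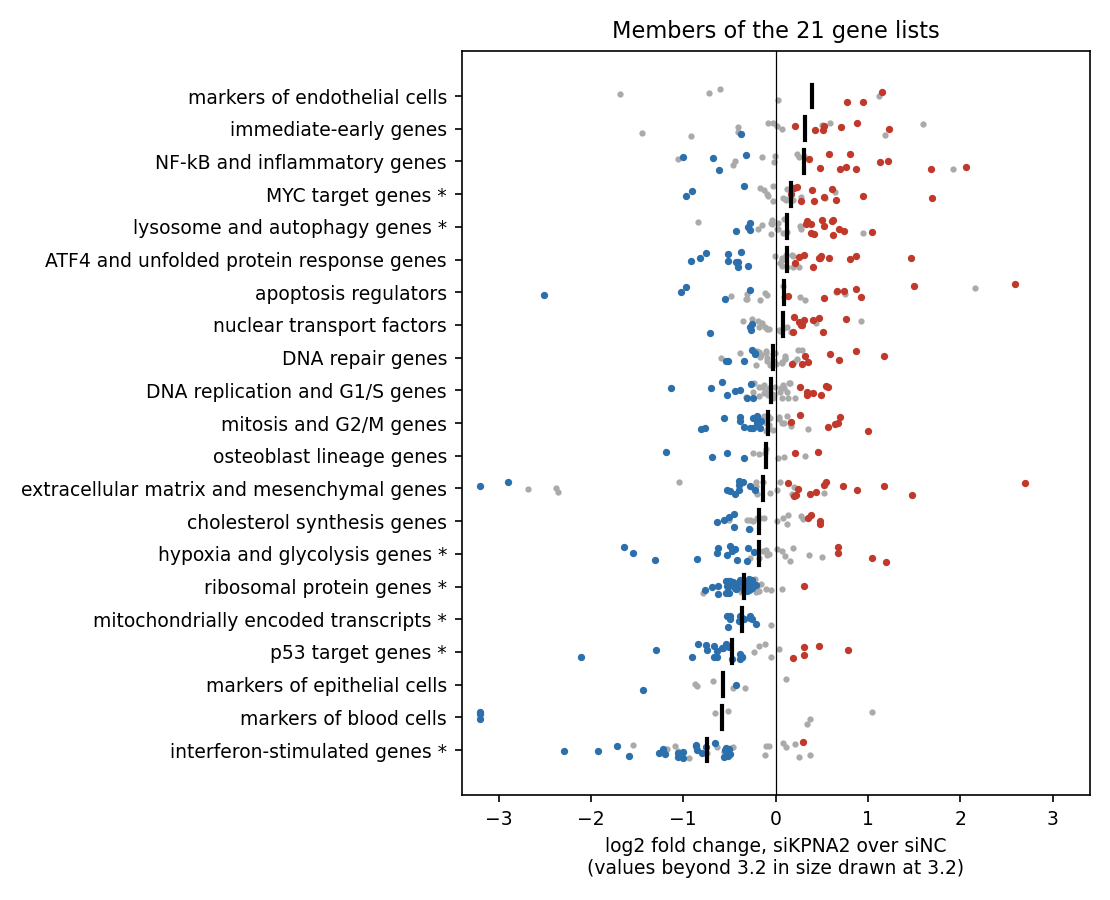
Log2 fold change of siKPNA2 over siNC for each tested member of the 21 gene lists, ordered by median. Red members rose, blue members fell, grey members did not pass the threshold, black bars are medians, and a star marks the 7 lists past the camera threshold; values beyond 3.2 in size are drawn at 3.2, and the interferon list has the lowest median at -0.75.

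The other 14 lists did not pass the camera threshold, but several held changed members in both directions. In NF-kB and inflammatory genes 11 of 25 rose and IER3, TNFAIP2, LIF and BCL3 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0727). The chemokine CXCL8 went from 34.8 ± 4.95 to 145 ± 22.4 CPM (SD, n = 3), and the NF-kB subunits NFKB1 (0.76, SE 0.06) and RELB (1.13, SE 0.10) rose. The GO term positive regulation of NF-kappaB transcription factor activity was enriched among lower genes, with 42 of 146 lower (28.8%, against 16.6% of the background; Fisher's exact test, adjusted p = 0.0203), among them CAV1 (-0.93, SE 0.05), TRIM22 and CLU. That call was lost in 5 alternatives, among them leaving out siKPNA2 replicate 3 or siNC replicate 1 or 2 (Fisher adjusted p of 0.00322 to 0.12 over all alternatives). In immediate-early genes 7 of 20 rose, among them EGR1 (1.22, SE 0.12), DUSP1 (0.88, SE 0.06) and FOSL1 (0.71, SE 0.06), and ZFP36 fell, a call lost in 3 alternatives (7 and 2 adjusted over the list alone; camera adjusted p = 0.0666). In apoptosis regulators 8 of 27 rose, including BCL2A1 and HRK (0.93, SE 0.08), and PMAIP1, BMF, CASP10, CASP8 and APAF1 fell, the last 3 with calls lost in 6, 5 and 9 alternatives (the same counts adjusted over the list alone; camera adjusted p = 0.223). In ATF4 and unfolded protein response genes 11 of 33 rose and 10 fell (14 and 10 adjusted over the list alone; camera adjusted p = 0.207): the chaperone HSPA5 (0.49, SE 0.04) and the transporter subunit SLC3A2 (0.87, SE 0.06) rose and CHAC1 fell (-0.92, SE 0.09). The longest annotated 3′ UTRs of IER3 and TNFAIP2 hold TGTCACG, as does that of HRK, and that of IER3 also holds TCCGAAA.

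Among nuclear transport factors, importin beta, KPNB1, went from 538 ± 6.06 to 746 ± 7.67 CPM and the importin alpha exporter CSE1L from 313 ± 4.26 to 447 ± 5.84 CPM (SD, n = 3). In that list 10 of 30 rose and XPO5 (-0.71, SE 0.05), RANBP2, IPO7 and XPO4 fell, the last with a call lost in 2 alternatives (11 and 5 adjusted over the list alone; camera adjusted p = 0.229). Cell cycle lists split: 7 of 40 mitosis and G2/M genes rose and 14 fell (8 and 15 adjusted over the list alone; camera adjusted p = 0.211), with CDC20 (-0.77, SE 0.05) and KIF20A (-0.81, SE 0.06) lower and BIRC5 (0.99, SE 0.08) higher. Of 43 DNA replication and G1/S genes 7 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.458), with LIG1 (-0.70, SE 0.06) and E2F2 (-1.13, SE 0.12) lower and CDC25A (0.55, SE 0.05) higher. Of 41 DNA repair genes 8 rose, among them XRCC4 (1.17, SE 0.12), RAD50 (0.87, SE 0.12) and PALB2 (0.59, SE 0.10), and 6 fell, also adjusted over the list alone (camera adjusted p = 0.914). The median of the repair list was -0.03 and its mean 0.03. The longest annotated 3′ UTRs of CSE1L and BIRC5 hold TGTCACG.

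In the matrix list 13 of 39 genes rose and 11 fell (13 and 12 adjusted over the list alone; camera adjusted p = 0.895): the collagen genes COL6A3, COL5A1 (1.17, SE 0.08) and COL4A1 (0.73, SE 0.05) rose, while COL6A1 (-0.44, SE 0.07), COL1A1 (-0.27, SE 0.07), SPARC (-0.40, SE 0.05) and THBS1 (-0.35, SE 0.05) fell, with the COL1A1 call lost in 3 alternatives. The GO term collagen-containing extracellular matrix was enriched among lower genes, with 75 of 263 lower (28.5%, against 16.6% of the background; Fisher's exact test, adjusted p = 0.000301), among them COL7A1 (-1.06, SE 0.08), CDH13 (-0.99, SE 0.07), whose 3′ UTR holds TGTCACG, and GDF15. The list's median (-0.14) and mean (-0.28) were below 0 while camera's direction was up. Of 13 osteoblast lineage genes, BMP2 (0.46, SE 0.06) and COL11A1 rose, and 4 fell, among them BMP4 (-0.69, SE 0.14), TNFRSF11B and ALPL (2 and 4 also adjusted over the list alone; camera adjusted p = 0.341). The calls of COL11A1, TNFRSF11B and ALPL were lost in 9, 5 and 6 alternatives. Of 24 cholesterol synthesis genes, HMGCS1 (0.47, SE 0.07), FDPS, PMVK and SQLE rose and 6 fell, among them STARD4 (-0.64, SE 0.10; 4 and 6 also adjusted over the list alone; camera adjusted p = 0.276). The calls of PMVK and SQLE were lost in 4 and 9 alternatives.

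Red cell transcripts were present in every siNC library and nearly missing from the siKPNA2 libraries. The 6 hemoglobin genes HBB, HBA1, HBA2, HBG1, HBG2 and HBD summed to 41.5 ± 3.38 CPM in siNC and 0.692 ± 0.341 CPM in siKPNA2 (SD, n = 3; exact permutation p = 0.1, the smallest possible). HBB, a beta globin (ENSG00000244734, chromosome 11, 5225464 to 5229395), had 1244, 1281 and 1300 counts in siNC and 21, 40 and 0 in siKPNA2. This was a 64.7-fold difference (95% interval 39.1 to 116). It was 128-fold without siKPNA2 replicate 2 (54.8 to 396) and 43.3-fold without siKPNA2 replicate 3 (26.1 to 77.7). CA1, the carbonic anhydrase of red cells, was 34.0-fold higher in siNC (21.6 to 56.9). The CA1 difference was 53.4-fold without siKPNA2 replicate 2 (26.9 to 124) and 24-fold without siKPNA2 replicate 3 (15.1 to 40.8). HBA1, with 11, 4 and 0 counts in siKPNA2, was 75.9-fold higher (29.4 to 281). The HBA1 difference was 204-fold without siKPNA2 replicate 1, which left 1 fragment (36.3 to 8070), and 50.8-fold without siKPNA2 replicate 3 (19.6 to 188). HBA2, with 7, 9 and 0 counts in siKPNA2, was 65.0-fold higher (25.1 to 240), and 43.5-fold to 87.2-fold without 1 siKPNA2 library. KLF1, an erythroid transcription factor chosen after its values were seen, had 242 counts in siNC and 0 in siKPNA2. With siKPNA2 set at the floor of 12 counts, KLF1 was 20.5-fold higher in siNC. The exact 95% interval of its ratio of siKPNA2 over siNC ran from 0 to 0.0624. These siNC libraries are the same ones in which the interferon, p53, ribosomal protein, mitochondrial and hypoxia groups were higher and the MYC and lysosome groups lower.

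Of 8 blood cell markers tested, HBA1, HBA2 and HBB fell and none rose (camera adjusted p = 0.104). Of 8 epithelial markers, KRT8 (-0.43, SE 0.05) and CLDN4 (-1.43, SE 0.38) fell and none rose (camera adjusted p = 0.141). Of 8 endothelial markers, ROBO4 (0.95, SE 0.12), TEK (1.16, SE 0.31) and TIE1 (0.77, SE 0.21) rose and none fell (camera adjusted p = 0.388). The counts of these 3 marker lists were the same adjusted over the list alone. The calls of CLDN4, TEK and TIE1 were lost in 10, 5 and 8 alternatives, and on log2(FPKM + 1) their log2 fold changes were -0.70, 0.22 and 0.24.

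Among annotation terms of lower genes, 67 of 131 tested genes of the KEGG term Ribosome fell (51.1%, against 18.8% of the background; Fisher's exact test, adjusted p = 5.43e-14). So did 47 of 125 genes of Oxidative phosphorylation (Fisher adjusted p = 0.000249) and 31 of 65 of the GO term respirasome (Fisher adjusted p = 4.06e-06). In respirasome HIGD2A, a complex IV assembly factor, went from 49.4 ± 2.25 to 15.4 ± 2.11 CPM (SD, n = 3). That term also counts MT-ND5 and MT-ND6, so it is not independent of the mitochondrial list. The p53 signaling pathway had 29 of 69 genes lower (adjusted p = 0.00182) and negative regulation of viral genome replication 19 of 37 (adjusted p = 0.000429), among them ZC3HAV1 (-0.55, SE 0.05), APOBEC3C (-0.65, SE 0.07), whose 3′ UTR holds TCCGAAA, and the kinase EIF2AK2 (-0.51, SE 0.06). The hemoglobin complex had 8 of 10 lower (adjusted p = 0.00363), and blood microparticle 29 of 62 (adjusted p = 1.71e-05), led by gelsolin, GSN (-1.22, SE 0.09), LGALS3BP and clusterin, CLU (-0.88, SE 0.07).

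Among higher genes, 25 of 54 genes of the IRE1-mediated unfolded protein response rose (46.3%, against 18.0% of the background; Fisher's exact test, adjusted p = 0.000519), with HDGF (0.48, SE 0.04), HSPA5 and KLHDC3 (0.67, SE 0.06). In protein processing in endoplasmic reticulum 48 of 155 rose (adjusted p = 0.0218), led by PPP1R15A, the stress-induced phosphatase subunit (1.85, SE 0.08), whose 3′ UTR holds TGTCACG, GANAB (1.79, SE 0.08) and RRBP1 (0.76, SE 0.05). In macroautophagy 31 of 91 rose (adjusted p = 0.0213), led by TOMM22 (1.38, SE 0.08), VPS4A (0.66, SE 0.05) and MFN1 (0.88, SE 0.07). Of 8272 tests, 104 terms passed, 18 among higher and 86 among lower genes. All of them compare the same libraries, of which those of siNC held more hemoglobin transcripts (41.5 against 0.692 CPM). The calls of macroautophagy, protein processing in endoplasmic reticulum, hemoglobin complex and viral genome replication were lost in 3, 7, 3 and 1 alternatives, with Fisher adjusted p over all alternatives of 0.00383 to 0.14, 0.00521 to 0.133, 0.00341 to 0.0878 and 0.000489 to 0.11. Leaving out siNC replicate 3 ended the first 3 of these calls, siKPNA2 replicate 2 ended protein processing and viral genome replication, siNC replicate 2 protein processing, and siKPNA2 replicate 3 and siNC replicate 1 hemoglobin complex.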

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

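Dividing the counts by 4 was the only alternative chosen after seeing the data. KPNA2 kept its direction and its call in all alternatives, with log2 fold changes of -5.28 to -4.97. The count of changed genes was 4630 to 6977 over all alternatives (6099 reported), with no gene called in opposite directions by an alternative and the reported fit, and terms numbered 71 to 145 (104 reported). Genes changed at least 2-fold numbered 306 on log2(FPKM + 1), where the pseudocount shrinks low genes, and 548 with a mean of at least 5 CPM, where 12237 genes were tested; without 1 library they numbered 1196 to 1296 (1431 reported). Gene lists past the threshold numbered 4 with a mean of at least 5 CPM, and the cause of that was not tested. They numbered 0 with camera's estimated correlation, where each of 7 had been called with the preset. The p53 list lost its call at an estimated correlation of 0.001, under the preset 0.01, so a higher correlation is not why. With fry, which does not compare a list with other genes, they numbered 16. DESeq2's test, limma-voom and dispersion that was not robust do not enter camera and gave no list value. With upper-quartile factors 45.6% of calls were higher, against 52.5% as reported, and no scaling moved the median log2 fold change past -0.06.

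With the replicate number as a block, 5064 genes were called, 1166 at least 2-fold, with 7 lists and 99 terms. Samples with the same number did not deviate together (correlations of -0.011, -0.008 and -0.005), so they share only a number, and no sample correlated best with its own number.

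Of 133 named genes besides KPNA2, 108 kept their direction and call in all of the up to 17 alternatives that gave them a value, and none changed direction. The calls of RNF185, CLDN4, TEK, TIE1, ALPL, ANKRD37, APAF1, ATG5, ATG9A, CASP10, CASP8, COL11A1, COL1A1, GADD45A, HSPE1, IFI44, NPC2, NPM1, PFKFB3, PMVK, SQLE, TNFRSF10B, TNFRSF11B, XPO4 and ZFP36 were lost in at least 1. Lists without a call were called by camera under another setting in 9 cases, 5 of them for immediate-early genes (camera adjusted p 0.0252 to 0.413), 3 for blood markers (0.0218 to 0.383) and 1 for NF-kB genes (0.0475 to 0.294); fry, which tests against no change, called 9 lists that camera did not. In the simulation, where 200 genes changed, 1.5-fold changes were mostly missed. The reported test called 6099 genes, so its cutoff on unadjusted p was looser. The simulated recovery therefore does not measure how many changes of that size it missed.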

Other observations

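Some tests here were chosen after the result was seen: whether U2OS cells themselves changed, and erythroid RNA against the interferon and p53 groups. The others so chosen were those of members lacking CCGAAA, of a control duplex, and of the erythroid markers against the share of all genes.

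Erythroid transcripts marked every siNC library. Of 30 further erythroid markers listed before their values were looked up, 24 had at least 12 counts on average in a group, and 16 of these were higher in every siNC library than in every siKPNA2 library (66.7%, against 23.8% of the 22930 genes of the table with as many counts; exact binomial p = 1.06e-05, one-sided), 1 was lower in every siNC library and 7 overlapped; 13 of the 30 lay at or above 1 CPM in siKPNA2, so U2OS cells express them too. GATA1 (33.7 counts on average) and HEMGN (45.3) had 0 counts in siKPNA2. Among the 16 higher markers, ANK1, EPOR, BPGM, TMCC2, FECH, CA2 and AQP1 lay at or above 1 CPM in siKPNA2. Their excess in siNC therefore need not come from erythroid cells. The rest of the 16 lay below 1 CPM in siKPNA2. A candidate source is RNA or reads of erythroid cells in the siNC libraries, which the 16 markers fit. A change of erythroid genes in U2OS cells themselves cannot be told apart from it, because every siNC library carries the signal: the highest siKPNA2 hemoglobin level was 0.0253 of the lowest siNC level.

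The lower interferon-stimulated and p53 target genes may be an effect of the knockdown, and 3 technical explanations were weighed. The series has no untransfected samples, so a fall after siKPNA2 cannot be told apart from a rise after siNC. A response of these genes to either siRNA itself was therefore not tested. Members lay 0.57 below 20 genes matched on length, GC content and level (median difference -0.57, 95% bootstrap interval -0.70 to -0.47), which argues against a bias by those. Erythroid RNA in the siNC libraries cannot be told apart from an effect of the knockdown. The members that fell lost 26.6 times the CPM that hemoglobin held in siNC. That ratio passed the limit set, after the result was seen, for arguing against such a source. The limit was not applied, because the share of globin in such a source was not measured. Members lacking CCGAAA in their longest annotated 3′ UTR had a median of -0.55 (-0.66 to -0.43, 50 of 57 members with a 3′ UTR). Matches to CCGAAA there are therefore not the whole cause. These bases were picked from the same fold changes and the siRNA sequences are not known, so matches to any other seed were not tested. That 5.1% of the members that fell held TCCGAAA (exact interval 0.6% to 17.3%), against 2.4% of genes of like 3′ UTR length, leaves open a small contribution, and an indirect effect through a regulator with a seed match was not tested.

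Both siRNAs may have left seed signatures, which is a hypothesis from these data. Over 11154 genes and 15889 heptamers, TCCGAAA in the 3′ UTR had the lowest rank z (-8.09; shuffles reached 5.43 in size), 2.25 times the strongest heptamer unlike it, and it occurs in the KPNA2 coding sequence (chromosome 17, 68042145 to 68042151, GRCh38), as 17.2% of heptamers do somewhere in KPNA2 transcripts; 90 of 230 genes holding it fell (39.1%), against 17.7% of the others. TGTCACG had the highest z (6.90, where shuffles reached 4.77), with 132 of 365 genes higher (36.2%, against 21.6%). GGAGAAA, which is unlike TGTCACG, came close (6.53), so that scan alone does not single out 1 seed. GGAGAAA shares GGAGA with TCGGAGA, which is taken up next, so its z does not argue against seed matches to both strands of 1 duplex. From general knowledge and not from the labels, a control duplex in common use has the sense strand TTCTCCGAACGTGTCACGT, and the matches to positions 2 to 8 of its antisense and sense strands, TGTCACG and TCGGAGA, ranked 1 and 7 (z of 6.90 and 5.26); both ranks had been seen when the duplex was recognised, so this decides nothing, and release from the control siRNA stays a possible explanation of part of the rises. Of the searched genes, TCCGAAA was held by 4.4% of the 2025 that fell and 8.7% of the 218 that fell at least 2-fold. TGTCACG was held by 5.4% of the 2464 that rose and 6.2% of the 258 that rose at least 2-fold. These shares count 1 heptamer in each direction. Related ones such as CCGAAAA (268 genes, z of -6.61) and TGTCACT (1922 genes, z of 5.92) were not counted. The shares therefore do not give the extent of any seed effect.

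Ribosomal protein genes lay below their 20 matched neighbours by a median difference of -0.236 (95% bootstrap interval -0.29 to -0.17), against -0.35 for the list itself, which leaves part of the shift open to level, length or GC content. By the same measure hypoxia and glycolysis genes differed by -0.21 (-0.37 to 0.0057), MYC targets by 0.15 (-0.0038 to 0.23) and lysosome and autophagy genes by 0.16 (-0.12 to 0.34), intervals that include 0.

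The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. For each of the 4 counts, 1 split, the real one, gave a count as large: 6099 changed genes against at most 4 in the others, 1431 changed at least 2-fold against at most 4, 7 lists against at most 4, and 104 terms against at most 0. Each of the 9 other splits had 1 to 4 lists past the camera threshold with the preset correlation, although at most 4 genes changed in any of them. Every other split mixes siKPNA2 and siNC libraries on both sides. Part of the treatment difference therefore stays between the sides, and the rest widens the spread within them. Their counts are not rates expected without a treatment effect.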
